A study of Mus musculus with 28 samples.

How the data were processed

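Gene expression was measured in the mouse cell line XEN-eYFP, a line of extraembryonic endoderm stem cells, after 96 h in 6 conditions. Total RNA (200 ng per sample) was labelled with biotin and hybridised to Illumina MouseWG-6 v2 BeadChips, 1 array per sample and 28 arrays in all. The conditions were medium alone (Media), 50 ng/ml recombinant Nodal, 100 ng/ml recombinant Cripto, the Alk4 inhibitor SB431542, Nodal with SB431542 and Cripto with SB431542. Each group held 5 arrays, except Nodal with SB431542, which held 3. The arrays came from 7 BeadChips, numbered here from 1 to 7. The labels give no dose for SB431542 and do not say whether the replicates of a group were separate cultures, so the p-values measure the spread between these samples.

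The deposited values per array are the bead-averaged signal, a linear intensity that was neither background-subtracted nor scaled between arrays, and per the file headers a detection p-value for each of 45281 probes. The detection p-value compares a probe with the negative control beads of its array and moves in steps of about 1 in 936. The authors also deposited processed values that behave as log2 intensities, with medians per array close to 7.86. These have the same rank order within each array as the signals, but the transformation behind them is not stated. BeadStudio and lumi are named per the labels, without versions.

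The signals were processed with limma 3.58.1 in R 4.3.3, with data.table (version 1.17.8) for reading the files. The neqc procedure estimated the background of each array from the detection p-values, since no control probes were among the files. It applied the normexp correction with an offset of 16, quantile normalisation over all probes and arrays, and a log2 transformation. Quantile normalisation gives all arrays the same distribution, so a change of total RNA output or of most genes in 1 direction cannot be seen on this scale. A probe was kept when its detection p-value was below 0.01 on at least 3 arrays, which left 18471 probes. Gene symbols came from a reference of gene names (assembly GRCm38.p6, used for names only), where 34885 probes matched exactly 1 symbol, 18 matched several and 10378 matched none. Where several probes matched a gene, the probe with the highest mean was taken. This left 9951 genes.

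Each gene was fitted with a linear model holding the group and the BeadChip as fixed terms, followed by eBayes moderation without trend or robust options (16 residual and 4.19 prior degrees of freedom). All tests were two-sided. A gene was called when its Benjamini-Hochberg adjusted p was below 0.05 over the genes of that comparison. The comparisons were each ligand against Media, SB431542 against Media, each ligand with SB431542 against SB431542 alone, each ligand with SB431542 against the ligand alone, Nodal against Cripto, and the interaction of each ligand with SB431542. Errors printed with log2 changes are limma standard errors. Where a gene was detected on none of the arrays of a group, it is called not above background there, and its fitted change depends on the offset. For such genes a lower bound of the fold is given, computed against the detection floor of the arrays. A gene detected on only some arrays of a group counts as measured, and the number of arrays is given with it. The size of its fitted change also depends on the background correction and the offset.

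The comparisons, tests, named-gene rule and gene lists were chosen before the data were examined. For each comparison the rule took the 10 genes with the largest rise and the 10 with the largest fall among called genes whose within-chip difference had the same sign on every chip holding both groups. For the interactions it took 5 called genes in each direction, and where no gene passed it took the 2 with the smallest p in each direction. Members of the lists could be named as well. The 21 lists hold 345 memberships and cover visceral, anterior visceral and parietal endoderm, primitive endoderm transcription factors, basement membrane, epithelial and mesenchymal genes, Nodal pathway components, targets of Smad2/3, BMP and Wnt, MAPK feedback and immediate early genes, mesendoderm and definitive endoderm, pluripotent epiblast, trophoblast, fibroblast feeder cells, cell cycle, cholesterol synthesis, glycolysis and hypoxia, the unfolded protein and integrated stress response, and the interferon response. They were tested with limma's camera at a preset correlation of 0.01, again with an estimated correlation, and with fry, and adjusted over the 21 lists within each comparison. A list is said to be called when camera called it at the preset correlation; fry, which does not compare a list with other genes, is given separately. Of the listed genes, 108 memberships had a probe on the array but none past the detection filter, and 29 had no probe named here.

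How much of a response persisted under the inhibitor was measured as the mean signed log2 change of the ligand's called genes in the comparison of ligand with SB431542 against SB431542 alone. The arrays used for choosing and for measuring these genes differ. Its p came from an exact permutation over all splits of the measured arrays, 56 splits for Nodal and 252 for Cripto, with the chip term kept. The splits also exchange arrays between chips. The p is therefore exact only if arrays of different chips are interchangeable apart from the chip term.

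On simulated data with normal noise of the fitted variance of each gene and 200 of 9951 genes changed, the fit for Nodal against Media recovered 53.7% of genes changed 1.5-fold, 97% of those changed 2-fold and 100% of those changed 4-fold. For Nodal with SB431542 against SB431542 the shares were 43.3%, 79.1% and 98.5%. For SB431542 against Media they were 50.7%, 86.6% and 100%, and for Cripto with SB431542 against Cripto 58.2%, 91% and 100%. False calls numbered 6, 7, 7 and 18 for these comparisons in the order given.

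The alternatives were no background correction, median centring in place of quantile normalisation, the authors' deposited values, no detection filter, a stricter detection filter, all probes tested singly, eBayes with trend and robust options, no chip term, chip as a random effect, only the compared groups in the fit, omission of chips 6 and 7, and omission of each array in turn. Further alternatives were chosen after the data were seen: chips 1 to 4 alone, chips 5 to 7 alone, omission of chip 5, omission of Media replicate 5 with SB431542 replicate 5, and array brightness as a covariate. The 10378 probes without a gene name took no part in the gene tests. Figures were drawn with matplotlib 3.10.9 and pandas 2.3.3 in Python 3.11.15.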

Results

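The series asks how Nodal and EGF-CFC signalling regulate extraembryonic endoderm stem cells. XEN cells are derived from the primitive endoderm, the tissue that forms visceral and parietal endoderm. Nodal is a ligand of the TGF-beta family that signals through Alk4 and Smad2/3, Cripto is an EGF-CFC protein that acts as a Nodal co-receptor, and SB431542 inhibits the kinase activity of Alk4. Expression of 9951 genes was compared between 5 Media, 5 Nodal, 5 Cripto, 5 SB431542, 3 Nodal with SB431542 and 5 Cripto with SB431542 arrays. The number of arrays limits the precision of every value.

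The mean signal per array ranged from 183.8 to 995 intensity units, and between 13191 and 16183 probes were detected. Group means of signal were 442.1 ± 150.7 (SD) for Media, 673.6 ± 223.5 for Nodal, 711.1 ± 269.4 for Cripto, 462.3 ± 169 for SB431542, 529.4 ± 95.1 for Nodal with SB431542 and 781 ± 102.8 for Cripto with SB431542. Within chips, Nodal arrays were 1.05 to 2.09 times as bright as the Media array and Cripto arrays 1.14 to 1.79 times. The first principal component held 53.4% of the variance. The second held 25% and separated the arrays of chips 1 to 4 (-51.9 to -1.1) from those of chips 5 to 7 (25.35 to 60.01). All Nodal with SB431542 arrays lay on chips 1 to 4, while every other group had arrays on both sets of chips. The fit holds the chip as a term. A score built from the genes called for Nodal averaged 0.825 ± 0.235 in Nodal, 0.984 ± 0.074 in Cripto and 0.995 ± 0.038 in Cripto with SB431542 arrays. It averaged -1.021 ± 0.027 in Media, -0.994 ± 0.031 in SB431542 and -1.073 ± 0.006 in Nodal with SB431542 arrays. The genes and their signs were taken from these same Nodal and Media arrays, so the distance between those groups was set by the choice.

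The comparison of Nodal with Media asks which genes respond to Nodal in XEN cells. Nodal-treated cells had higher expression of visceral endoderm and epithelial genes and of feedback genes of the MAPK pathway, and lower expression of parietal endoderm genes and of enzymes of cholesterol synthesis (adjusted p = 0.055 for the last with an estimated correlation). The largest rises included Gpc3, a cell-surface glypican (log2 change 5.89 ± 0.18), the tight junction gene Cldn6 (5.42 ± 0.18, 42.7-fold), Cyp26a1, which degrades retinoic acid (5.14 ± 0.21), and Ddc, a decarboxylase of aromatic amino acids (5.05 ± 0.13). Cpn1 (5.51 ± 0.20), Spsb1 (4.84 ± 0.21) and Clic6 (4.81 ± 0.14) rose as well. Of the 5 Media arrays, Cyp26a1 and Spsb1 were detected on 1, Gpc3 on 2, and Cpn1 and Ddc on 4, so the size of these rises depends on the background correction. The peptidase gene Dpp4, the ubiquitin ligase gene Rnf130 and the protease inhibitor gene Spint1 were detected on no Media array and were at least 29-fold, 35-fold and 21.6-fold higher.

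The largest falls included the transcription factor gene Sox5 (log2 change -5.00 ± 0.15), the chromatin organiser gene Satb1 (-4.75 ± 0.13), the kinase gene Tnik (-4.37 ± 0.14) and Igfbp5, which encodes a binding protein of insulin-like growth factors (-4.65 ± 0.31). Sox5 and Tnik were detected on 2 of 5 Nodal arrays, so the size of their falls depends on the background correction. Tmem176b, Sdk1, Pmch, Acss1, Napsa and Btn1a1 were detected on no Nodal array and were at least 29.7-fold, 21.4-fold, 16.6-fold, 14.1-fold, 13.6-fold and 10.4-fold lower. The adjusted p of these 20 genes in limma was at most 6.42e-11, for Igfbp5.

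Of 19 measured visceral endoderm genes, 12 rose and 4 fell after Nodal (median log2 change 1.39). The endocytic receptor genes Lrp2 (2.73), Amn (2.67) and Cubn (2.0) rose, as did Spink1 (4.40), Cdh1, which encodes E-cadherin (2.04; detected on 3 of 5 Media arrays), and the transcription factor gene Hnf4a (1.32). The 4 genes of the list that fell were Apoa1 (-2.64; detected on 4 of 5 Nodal arrays), Ttr (-1.19), and Trf and Afp (at least 2.31-fold and 1.78-fold). Of 11 epithelial genes, 8 rose and 1 fell (median 1.73, or 1.19 with genes not above background set to their bound), among them the keratin genes Krt19 (2.73) and Krt18 (1.56), while Rab25 fell (-0.63; detected on 2 of 5 Media arrays and 1 of 5 Nodal arrays). Of 16 MAPK feedback and immediate early genes, 13 rose (median 1.43, or 1.22 with bounds), including the phosphatase genes Dusp4 (3.65) and Dusp6 (2.64). Dusp4 was detected on 1 of 5 Media arrays and averaged 5.52 there, below the lowest detection floor (5.55), so the size of its change is uncertain. Etv4 and Etv5 of the same list were at least 4.1-fold and 2.9-fold higher. Of 17 cell cycle genes, 11 rose (median 0.58), such as Aurka (1.15) and Cdk1 (1.06).

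Of 16 parietal endoderm genes, 10 fell and 1 rose after Nodal (median -0.48). The basement membrane gene Nid1 (-4.16), the retinol transporter gene Stra6 (-1.98), Plat (-1.08), Thbd (-1.06), Snai1 (-0.89) and Sox7 (-0.87) fell, while the collagen gene Col4a2 rose (1.60; detected on 3 of 5 Media arrays). Of 12 cholesterol synthesis genes, 10 fell (median -1.0), including Mvd (-1.91), Fdps (-1.39) and Sqle (-1.25). Of 6 interferon response genes, 5 fell (median -0.74, or -0.72 with bounds), with Usp18 at -2.45 (detected on 1 of 5 Nodal arrays). Rab25 and Usp18 averaged 5.34 and 5.17 in Nodal, below the lowest detection floor as well, so the size of these falls is uncertain. The camera adjusted p was 0.0045 for visceral endoderm, 0.00068 for epithelial genes, 1.1e-05 for MAPK feedback, 0.012 for cell cycle, 0.0044 for parietal endoderm, 0.00098 for cholesterol synthesis and 0.038 for the interferon response. With an estimated correlation, 5 of these 7 lists were called; the adjusted p was 0.055 for cholesterol synthesis and 0.15 for the interferon response. The numbers of genes that rose and fell on these 7 lists were the same when adjusted over the list alone.

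In all, limma called 5727 genes for Nodal against Media, 2851 higher and 2876 lower, of which 1737 changed at least 2-fold. The split between directions depends on the scaling. Centring each array on its median in place of quantile normalisation shifted the median of all genes by 0.45 and gave 5042 higher and 1156 lower genes, so the changes above are relative to the median gene of quantile-normalised arrays. None of the 7 lists changed direction with that scaling, but the median became 1.14 for cell cycle, -0.61 for cholesterol synthesis and -0.38 for the interferon response. Sizes also depended on the background: without its correction the medians were 0.89 for visceral endoderm, 0.75 for epithelial genes and 0.58 for MAPK feedback, and with the authors' deposited values 0.72, 0.52 and 0.5. Without the detection filter they were 0.44, 0.45 and 1.37. For the interferon response the median was -0.44 without background correction and -0.41 with the deposited values. Within the 5 chips holding both groups, the list medians ranged from 1.21 to 1.87 for visceral endoderm, from 1.18 to 2.68 for epithelial genes, from 0.97 to 1.43 for MAPK feedback and from 0.34 to 0.74 for cell cycle. They ranged from -0.53 to -0.36 for parietal endoderm, from -1.14 to -0.70 for cholesterol synthesis and from -1.29 to -0.69 for the interferon response. The interferon call was lost on 6 other settings, with adjusted p of 0.0508 (without Media replicate 1) to 0.114. Nodal replicate 1 had the smallest response of its group, with a score of 0.405 against 0.908 to 0.95 in the others.

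**Figure D1:**
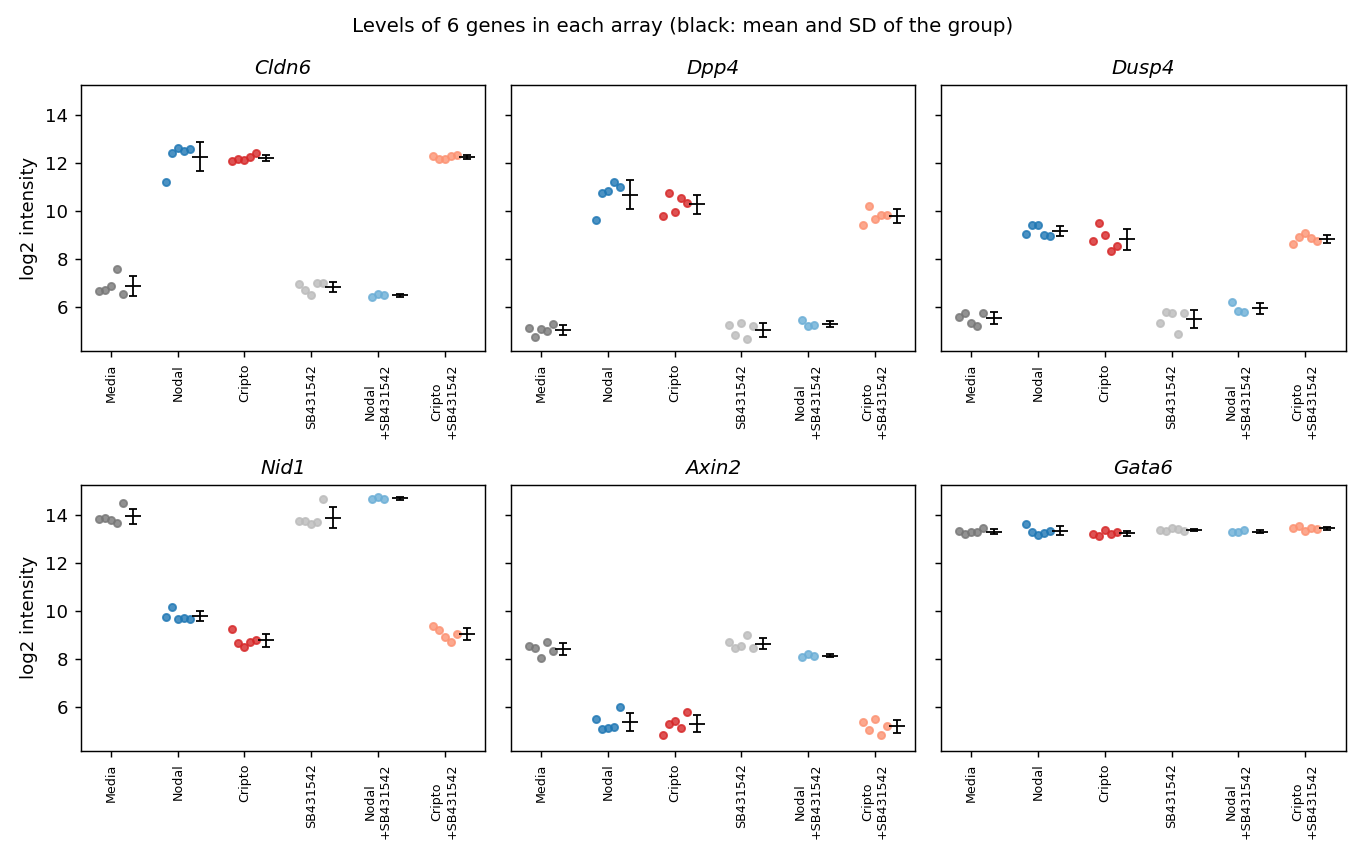
Normalised log2 intensity of 6 genes from the fixed lists in each of the 28 arrays (points) with the mean and SD of each group (black). Cldn6, Dpp4 and Dusp4 are high and Nid1 and Axin2 low in the Nodal, Cripto and Cripto with SB431542 groups, whereas Gata6 lies between group means of 13.25 and 13.46 in all 6 groups.

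The comparison of Cripto with Media asks whether the EGF-CFC protein, added without Nodal, changes the same cells. Cripto-treated cells had higher expression of MAPK feedback, cell cycle, epithelial and visceral endoderm genes and lower expression of parietal endoderm and cholesterol synthesis genes (adjusted p = 0.15 for the last with an estimated correlation). Cpn1 (log2 change 5.56 ± 0.20), Gpc3 (5.51 ± 0.19), Cldn6 (5.39 ± 0.19), Spsb1 (5.32 ± 0.22), the imprinted gene Phlda2 (5.21 ± 0.16) and Ddc (5.19 ± 0.14) rose. Rnf130, Dpp4, the imprinted gene Grb10 and the complement protease gene Masp1 were at least 42.6-fold, 21.8-fold, 21.7-fold and 19.4-fold higher. Among genes above background, Igfbp5 had the largest fall (-6.76 ± 0.31, 108-fold), followed by Spink4 (-5.67 ± 0.28), Nid1 (-5.14 ± 0.17), Satb1 (-5.06 ± 0.13), the colipase gene Clps (-5.02 ± 0.17) and Cep112 (-4.94 ± 0.12). Tmem176b, Sdk1, Pmch and Acss1 were at least 27.9-fold, 20.2-fold, 15.6-fold and 13.3-fold lower. Spink4, Satb1 and Cep112 were detected on 3, 4 and 2 of 5 Cripto arrays. The size of their falls, and of the rises of Gpc3 and Spsb1 against their Media level, depends on the background correction. The adjusted p of these 20 genes was at most 2.66e-07, for Grb10.

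Of the MAPK feedback genes, 12 rose and 1 fell after Cripto (median 1.30, or 1.14 with bounds; adjusted p = 0.00065), including Dusp4 (3.29, against the same Media level) and Dusp6 (1.42). Of the cell cycle genes, 13 rose and 1 fell (median 0.61; adjusted p = 0.0016), including Ccne1 (2.02), Aurka (1.64) and Cdk1 (1.56). Of the parietal endoderm genes, 12 fell and 2 rose (median -0.55; adjusted p = 0.0026), with Stra6 at -1.69 and Sox7 at -1.41. Of the epithelial genes, 8 rose and 1 fell (median 1.18, or 0.72 with bounds; adjusted p = 0.0046), with Krt19 at 1.87 and Krt18 at 1.65. Of the cholesterol synthesis genes, 9 fell (median -0.81, or -0.49 with bounds; adjusted p = 0.016), with Idi1 at -1.42 (detected on 3 of 5 Cripto arrays). Of the visceral endoderm genes, 12 rose and 5 fell (median 1.15; adjusted p = 0.027), with Spink1 at 4.85, Lrp2 at 2.22 and Cubn at 2.21. With an estimated correlation 5 of these 6 lists were called, and the adjusted p for cholesterol synthesis was 0.15. The visceral endoderm call was lost with median centring (adjusted p = 0.088) and with the authors' deposited values (adjusted p = 0.0592). Numbers adjusted over the list alone were the same for these 6 lists.

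In limma 6421 genes were called for Cripto against Media, 3185 higher and 3236 lower, and 2451 changed at least 2-fold. With median centring the shift of all genes was 0.44, and 4979 genes were higher and 1536 lower. The list medians then became 1.15 for cell cycle and -0.22 for cholesterol synthesis. Without background correction the medians were 0.53 for MAPK feedback, 0.64 for epithelial, 0.45 for visceral endoderm and -0.44 for cholesterol synthesis genes, and with the deposited values 0.36, 0.45, 0.4 and -0.4. Parietal endoderm had -0.84 with the deposited values. Without the detection filter the medians were 0.62 for epithelial and 0.45 for visceral endoderm genes. Within the 4 chips holding both groups, the list medians ranged from 1.07 to 1.31 for MAPK feedback, from 0.61 to 0.92 for cell cycle, from -0.62 to -0.59 for parietal endoderm, from 0.82 to 1.69 for epithelial genes, from -1.12 to -0.60 for cholesterol synthesis and from 0.80 to 1.74 for visceral endoderm.

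The responses to the proteins overlapped. Called in both with the same sign were 4880 genes, 2368 higher and 2512 lower, where 1848 would be found if the 2 sets were independent, and 41 genes were called with opposite signs. Both comparisons use the same Media arrays, which by itself gives a correlation. Across genes, which are not independent replicates, the log2 changes had a correlation of 0.924 and a covariance of 0.821. Simulated unchanged groups against shared controls gave 0.485 and 0.0146, and no gene called in both. With the Media arrays split between the comparisons the correlation was 0.861 to 0.891 and the number of shared genes 3295 to 3783 over 20 splits.

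The comparison of SB431542 with Media asks whether the inhibitor alone alters XEN cells. Neither camera nor fry called a list (0 of 21), and limma called 0 of 9951 genes. The mesendoderm list (3 genes, median 0.12, adjusted p = 0.0934) was called on 4 other settings (adjusted p of 0.00519 to 0.0244) and without Media replicate 4 (0.0354), SB431542 replicate 4 (0.016) or SB431542 replicate 5 (0.0388), and pluripotent epiblast genes without the chip term (0.0445). At an unadjusted p under 0.05 there were 270 genes, where 498 are expected by chance. This count lies below chance and does not measure an absence of effect. The spread of each gene was estimated over all 6 groups, with Media replicate 5 and SB431542 replicate 5 included. The 95% confidence interval lay within 2-fold for 97.9% of genes. The genes with the smallest p in each direction were Mis12 (log2 change 0.73 ± 0.14, adjusted p = 0.295), Gtf2b (0.56 ± 0.13, adjusted p = 0.922) and Prcc (-0.64 ± 0.16, adjusted p = 0.922), and Slc29a2, not above background with SB431542 (at least 1.13-fold, adjusted p = 0.922). The other detected probe of Prcc changed in the opposite direction. Mis12 and Gtf2b were detected on 3 of 5 arrays in each group, Prcc on 3 of 5 SB431542 arrays and Slc29a2 on 4 of 5 Media arrays. Without SB431542 replicate 5, 1 gene was called.

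The comparisons with the inhibitor present ask whether the responses to each protein persist with SB431542. Whether Alk4 is the only target of the inhibitor in these cells was not tested. Under SB431542, Nodal left the Nodal response genes near the level of the inhibitor alone. The mean signed change of the 5727 genes was 0.923 without and -0.025 with the inhibitor, -2.7% of the original. The exact two-sided permutation p for the latter was 0.464 over 56 splits, and per chip the value was -0.03, -0.03 and -0.04. It was -0.042 without the chip term (exact p = 0.0179), -0.074 with brightness as a covariate (exact p = 0.0357) and -0.053 to -0.001 with 1 array left out (exact p of 0.143 to 0.982). With the inhibitor 48.9% of the genes kept their direction. Cldn6, at 12.28 ± 0.59 log2 units in Nodal, was at 6.48 ± 0.07 in Nodal with SB431542 and 6.87 ± 0.41 in Media. Dpp4 was not detected on any Media array, averaged 10.70 ± 0.62 in Nodal arrays and 5.29 ± 0.13 in Nodal with SB431542 arrays.

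The comparison of Nodal with SB431542 against Nodal alone shares the 5 Nodal arrays with that of Nodal against Media, which by itself gives changes of opposite sign. Cpn1 (log2 change -6.65 ± 0.25), Gpc3 (-5.78 ± 0.22), Cldn6 (-5.65 ± 0.23), Ddc (-5.50 ± 0.16) and Phlda2 (-5.15 ± 0.19) were lower. Rnf130, Dpp4, the carbonic anhydrase gene Car4, Cyp26a1 and Spint1 were at least 39.1-fold, 32.4-fold, 31.2-fold, 28.2-fold and 24.1-fold lower. Nid1 (4.98 ± 0.21), Tnik (4.73 ± 0.17), Satb1 (4.73 ± 0.16), Ikzf1 (4.70 ± 0.34) and Sox5 (4.68 ± 0.18) were higher, and Pmch, Tmem176b, Sdk1, Klre1 and Acss1 were at least 29.7-fold, 27-fold, 18-fold, 16-fold and 12.3-fold higher. Of the 3 Nodal with SB431542 arrays, Cpn1 and Phlda2 were detected on 1 and Gpc3 and Ddc on 2, and of the 5 Nodal arrays Ikzf1 on 1 and Tnik and Sox5 on 2. The size of these 7 changes depends on the background correction, since Cpn1 and Phlda2 averaged 5.51 and Ikzf1 5.47, below the lowest detection floor (5.55), and Gpc3 (5.58), Sox5 (5.68), Tnik (5.66) and Ddc (5.79) lay close to it. These 20 genes had adjusted p of at most 4.42e-10, for Ikzf1. Of the visceral endoderm genes 12 fell and 4 rose (median -1.78; adjusted p = 0.003), of the epithelial genes 8 fell (-1.90, or -1.34 with bounds; 0.00029), and of the MAPK feedback genes 12 fell and 2 rose (-1.41, or -1.12 with bounds; 0.00029). Of the cell cycle genes 10 fell and 1 rose (-0.68; 0.026). Of the parietal endoderm genes 10 rose and 2 fell (0.53; 0.003), and of the cholesterol synthesis genes 9 rose (1.02; 0.0016). With an estimated correlation the adjusted p for cholesterol synthesis was 0.066 and the other 5 lists were called. Adjusted over the list alone, 13 MAPK feedback genes fell, 1 epithelial gene rose, and the other numbers were the same.

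In limma 5338 genes were called for Nodal with SB431542 against Nodal, 2588 higher and 2750 lower, and with median centring (shift -0.33) 1417 were higher and 3757 lower, with a cell cycle median of -1.08. Without background correction the medians were -1.05 for visceral endoderm, -0.94 for epithelial genes and -0.63 for MAPK feedback, and with the deposited values -0.83, -0.66 and -0.48, with -0.45 for cell cycle. Without the detection filter they were -0.43 for visceral endoderm and -0.41 for epithelial genes. With only these 2 groups in the fit the count was 1661, and the cell cycle list was no longer called (adjusted p = 0.0825). On the 2 chips holding both groups the medians were -1.93 and -1.43 for visceral endoderm, -2.54 and -1.81 for epithelial genes, -1.32 and -1.24 for MAPK feedback, -0.58 and -0.35 for cell cycle, 0.51 and 0.59 for parietal endoderm, and 1.01 and 1.24 for cholesterol synthesis.

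The Cripto response, in contrast, was present with the inhibitor. Of the 6421 Cripto response genes, 96.8% changed in the same direction under SB431542, with a mean signed change of 0.972 against 1.021 without it (95.1%). The exact two-sided permutation p was 0.00794, the smallest that the 252 splits can give, and per chip the mean was 1.0, 0.99 and 1.01. Against SB431542 alone, Cripto with SB431542 raised Cpn1 (log2 change 6.05 ± 0.21), Ddc (5.76 ± 0.14), Gpc3 (5.51 ± 0.19), Phlda2 (5.44 ± 0.17), Cldn6 (5.42 ± 0.19) and the troponin gene Tnnc1 (5.36 ± 0.22). Rnf130, Lypd10, Prxl2a and Masp1 were at least 40.2-fold, 29.3-fold, 24.6-fold and 22.1-fold higher. Igfbp5 (-6.72 ± 0.32), Satb1 (-5.23 ± 0.14), Clps (-5.16 ± 0.17) and the collagen gene Col6a1 (-5.08 ± 0.32) fell. Spink4, Tmem176b, Sdk1, Tnik, Pmch and Acss1 were at least 54.4-fold, 27.8-fold, 20.3-fold, 16.8-fold, 16.6-fold and 14.2-fold lower. Ddc, Gpc3, Cpn1 and Phlda2 were detected on 2, 3, 4 and 4 of 5 SB431542 arrays, and Satb1 on 3 of 5 Cripto with SB431542 arrays, so the size of these changes depends on the background correction. The adjusted p of these 20 genes was at most 3.45e-10, for Lypd10.

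**Figure D2:**
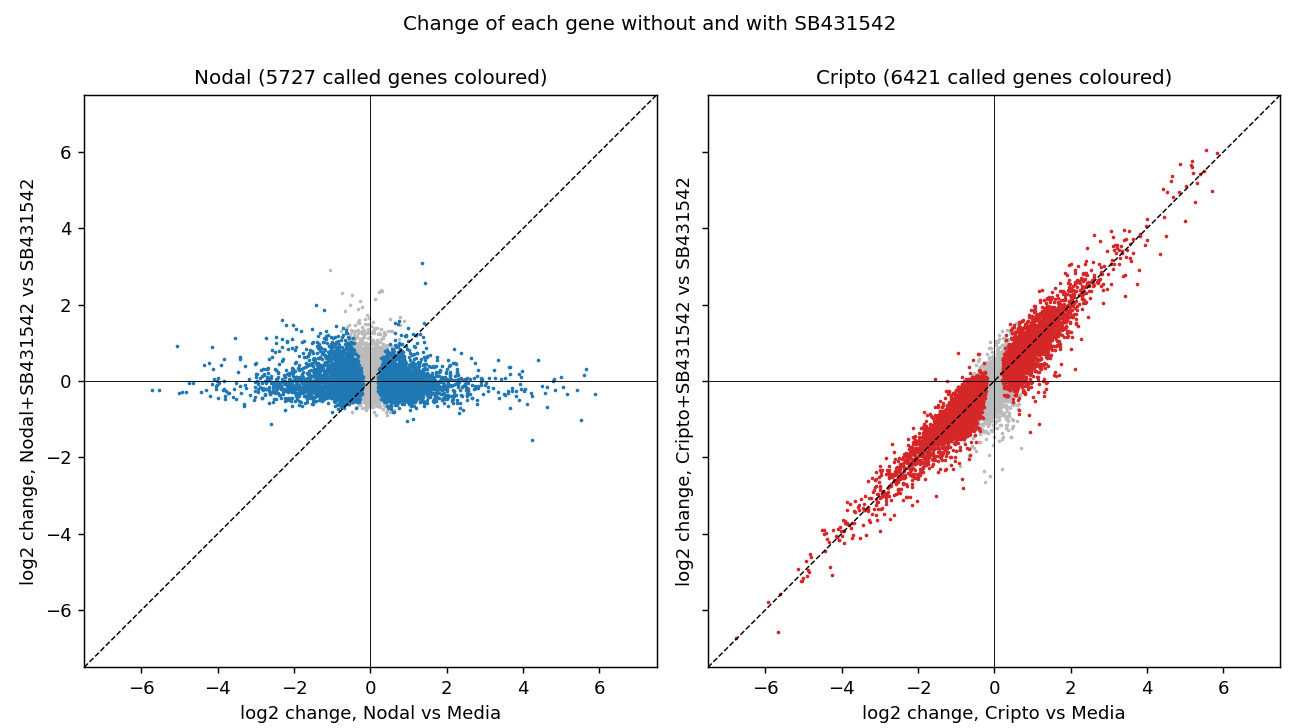
Log2 change of each of the 9951 genes for Nodal (left) and Cripto (right) against Media (horizontal axis) and, with SB431542 present, against SB431542 alone (vertical axis); genes called against Media are coloured and the dashed line marks equal changes. Nodal response genes lie along the horizontal axis (correlation across all genes -0.064), and Cripto response genes along the dashed line (0.936).

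The 6 lists called for Cripto alone were called again in the same direction, and BMP targets were called in addition; the difference from Cripto alone was tested by the interaction, for which camera called no list. MAPK feedback genes (12 rose, 2 fell; median 1.16, or 1.10 with bounds; adjusted p = 0.0023), epithelial genes (8 rose, 1 fell; 1.53, or 1.06 with bounds; 0.004) and cell cycle genes (11 rose, 1 fell; 0.72; 0.005) rose. Parietal endoderm (13 fell, 1 rose; -0.74; 0.0029) and cholesterol synthesis genes (10 fell; -0.88, or -0.66 with bounds; 0.005, and 0.1 with an estimated correlation) fell. Visceral endoderm genes (11 rose, 4 fell; 1.42; 0.042) and BMP target genes (4 of 5 rose; 1.41; 0.042), among them Id1 (2.10), Id3 (1.47; detected on 1 of 5 SB431542 arrays at a mean of 5.17, below the lowest detection floor, so its size is uncertain) and Nog (1.41), were called with the preset correlation. With an estimated correlation the adjusted p was 0.064 for visceral endoderm and 0.082 for BMP targets, and the other 4 lists were called. The visceral endoderm call was lost on 5 of the other settings (adjusted p of 0.0545 to 0.0871) and the BMP call on 7 (0.0513 to 0.0765), and the BMP call also without SB431542 replicate 3 (0.0554) or without Cripto with SB431542 replicate 3 (0.0538). Without background correction the medians were 0.63 for visceral endoderm, 0.51 for BMP targets, 0.63 for epithelial, 0.68 for MAPK feedback and -0.56 for cholesterol synthesis genes. With the deposited values they were 0.46, 0.34, 0.46, 0.51 and -0.48. Without the detection filter they were 0.22 for visceral endoderm, 0.13 for BMP targets and 0.49 for epithelial genes. With median centring they were 1.16 for cell cycle and -0.42 for cholesterol synthesis. Numbers adjusted over the list alone were the same for these 7 lists.

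In limma 6521 genes were called for Cripto with SB431542 against SB431542, 3166 higher and 3355 lower, and with median centring (shift 0.31) 4295 higher and 1910 lower. Called in this comparison and in Cripto against Media were 5377 genes with the same sign and 20 with opposite signs, where 2104 would share their sign if the sets were independent. The groups of these comparisons share no array, but both come from the same fit with its chip terms. On the 3 chips holding both groups, the medians ranged from 1.24 to 1.30 for MAPK feedback, from 1.23 to 1.66 for epithelial genes, from 0.56 to 0.83 for cell cycle, from -0.63 to -0.57 for parietal endoderm, from -0.94 to -0.70 for cholesterol synthesis, from 1.21 to 1.66 for visceral endoderm and from 1.16 to 1.41 for BMP targets.

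The interaction terms test whether the responses differ with and without the inhibitor. For Nodal, 4365 genes were called, 2137 higher and 2228 lower, and with median centring (shift -0.34) 1044 and 2942. For Cripto, 65 genes were called, 28 higher and 37 lower, and camera and the directional test of fry called 0 of 21 lists. The fry test for changes in either direction called 2, Smad2/3 targets (adjusted p = 0.009) and the stress response (0.024). The Cripto number varied between 9 and 216 when 1 array was left out, moving by more than 1.5 times in 15 of 20 cases, and median centring left 2 genes.

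Cripto with SB431542 differed from Cripto alone in 856 genes, 420 higher and 436 lower. Of these, 110 changed at least 2-fold, 7 higher and 103 lower. Taf15 (log2 change 1.46 ± 0.15), Prrc2c (1.39 ± 0.19), the folate receptor gene Folr1 (1.25 ± 0.23), Txnip (1.20 ± 0.29), the integrin gene Itgb4 (1.17 ± 0.26), the actin-severing gelsolin gene Gsn (1.15 ± 0.15), Fbxo2 (1.02 ± 0.27), Socs3 (0.97 ± 0.12) and Cd55 (0.96 ± 0.28) were higher, and Cckbr at least 1.15-fold. Slc25a36 (-2.47 ± 0.52), Ccdc25 (-2.34 ± 0.43), Nop10 (-2.33 ± 0.43), Smarcc1 (-2.29 ± 0.58), Bcap31 (-2.18 ± 0.44), Arhgdib (-2.03 ± 0.39), Tent5a (-1.98 ± 0.36), Tmem216 (-1.87 ± 0.27), Mrpl48 (-1.82 ± 0.36) and Capza1 (-1.81 ± 0.34) were lower. The other detected probe of Smarcc1 changed in the opposite direction. Of the 5 Cripto with SB431542 arrays, Arhgdib was detected on 1, Ccdc25 on 3, and Slc25a36, Capza1 and Cckbr on 4, so the size of these changes depends on the background correction. Of the 21 lists, camera called 0. The directional test of fry called 1, mesendoderm and definitive endoderm (higher; median 0.13; adjusted p = 0.037). Its test for changes in either direction called 6: Smad2/3 targets (adjusted p = 6.4e-08), the stress response (0.00023), parietal endoderm (0.0033), cell cycle (0.0085), basement membrane (0.016) and primitive endoderm transcription factors (0.032). Median centring (shift -0.08) gave 54 higher and 251 lower genes, and the number fell to 314 without Cripto replicate 2, 465 without Cripto replicate 3, 249 without Cripto with SB431542 replicate 1 and 497 without Cripto with SB431542 replicate 4. Other detected probes of the same genes changed by 56.2% as much as the chosen ones, against 85.1% for Nodal response genes matched in size.

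Nodal with SB431542 against SB431542 alone asks what Nodal does when the inhibitor is present. Called were 366 genes, 318 higher and 48 lower. The RhoA exchange factor gene Net1 (log2 change 3.09 ± 0.56), the splicing factor genes Sfpq (2.90 ± 0.58) and Srsf10 (2.14 ± 0.42), the tRNA synthetase gene Eprs (2.58 ± 0.70), the transporter gene Slc6a15 (2.38 ± 0.50), Hif1a (2.37 ± 0.54), Smarca5-ps (2.33 ± 0.43), 4932438A13Rik (2.26 ± 0.54), the catenin gene Ctnnd1 (2.10 ± 0.58) and Lpp (2.0 ± 0.43) were higher. Maea (-1.05 ± 0.20), Cpn1 (-1.03 ± 0.24), Ccndbp1 (-1.0 ± 0.17), Rrp9 (-0.80 ± 0.17), Plpbp (-0.76 ± 0.16), Rcc1 (-0.73 ± 0.17), Nfe2l2 (-0.71 ± 0.19) and Ankrd1 (-0.71 ± 0.13) were lower, Car4 at least 1.65-fold. Tead3 was called lower but was not above background in Nodal with SB431542 arrays, and no bound could be given. Their adjusted p ranged from 0.0121 to 0.0487. Neither of 2 other detected probes of Slc6a15 nor the other probe of Ccndbp1 changed in the same direction, and for Eprs, 4932438A13Rik, Cpn1 and Plpbp 1 of 2 did, for Lpp 2 of 3 and for Srsf10 3 of 4. Of the 5 SB431542 arrays, Sfpq and Slc6a15 were detected on 1, Net1 and Tead3 on 2, Hif1a on 3, and Smarca5-ps, 4932438A13Rik, Cpn1 and Car4 on 4. Cpn1 was detected on 1 of 3 Nodal with SB431542 arrays. The size of the changes of these genes depends on the background correction. Of the 21 lists, camera and fry called 0. Of the 203 genes also called for Nodal against Media, 51 had the same sign and 152 the opposite sign.

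These calls rest on single arrays. The number was 103, 33, 0, 129 and 607 without SB431542 replicates 1 to 5, and 0, 1 and 6 without Nodal with SB431542 replicates 1 to 3. It was 76 with median centring, where Slc6a15 changed direction (-0.40), 3 without the chip term, 43 without chip 5 and 227 without the detection filter. It was 1594 with only these 2 groups in the fit, 818 without Media replicate 5 and SB431542 replicate 5, 711 without chips 6 and 7, and 675 with all probes tested singly. In 538 genes chosen for this difference from chips 1 to 4 alone, Media replicate 5 and SB431542 replicate 5, labelled as without Nodal, were shifted by 73.7% and 87.8% of the shift of the Nodal with SB431542 arrays. The latter arrays also chose the genes, which can enlarge their shift. In genes chosen without the array measured, the held-out Nodal with SB431542 arrays shifted by 1.07 to 1.08. Media replicate 5 then shifted by 1.01 to 1.04 and SB431542 replicate 5 by 1.09 to 1.12.

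Nodal and Cripto were applied at different doses, 50 and 100 ng/ml, so their direct comparison does not separate the protein from its dose. Higher in Nodal than in Cripto were the kinase gene Alpk3 (log2 change 2.33 ± 0.28), Igfbp5 (2.11 ± 0.31), the water channel gene Aqp1 (2.10 ± 0.19), Hif3a (2.07 ± 0.18), the glutathione-degrading gene Chac1 (2.06 ± 0.16), Msmb (1.98 ± 0.18), Mgarp (1.96 ± 0.19) and the lipoprotein receptor gene Vldlr (1.87 ± 0.13). The glycogen phosphorylase gene Pygl and Stk32c were at least 2.79-fold and 2.59-fold higher. Lower in Nodal were Acot7 (-2.17 ± 0.11), Lor (-2.13 ± 0.28), Depp1 (-1.85 ± 0.16), Mybpc3 (-1.63 ± 0.26), the netrin receptor gene Unc5b (-1.63 ± 0.24), Gadd45b (-1.60 ± 0.14), Icam1 (-1.41 ± 0.24) and Nab2 (-1.40 ± 0.26), and Rpph1 and Map6 at least 2.38-fold and 1.6-fold. Msmb, Hif3a and Map6 were detected on 2, 4 and 4 of 5 Cripto arrays, and Pygl and Icam1 on 4 of 5 Nodal arrays, so the size of these differences depends on the background correction. The adjusted p of these 20 genes was at most 0.000529, for Nab2. On chip 1 the Nodal array was close to the Cripto array in several of them, with a difference of 0.09 for Igfbp5 and 0.161 for Pygl.

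Of 15 genes of the unfolded protein and integrated stress response, 10 were higher in Nodal than in Cripto and 1 was lower (median 0.37; adjusted p = 6.4e-05). Trib3 was 1.01 and Herpud1 0.85 higher, and Atf3 was lower (-1.26). Of these, Chac1 rose with Nodal (1.74) and was at -0.31 with Cripto against Media, while Vldlr fell with both, by -1.41 and -3.27. Of 17 cell cycle genes, 7 were lower in Nodal (median -0.37; adjusted p = 0.0054), among them Ccne1 (-1.19). Of 12 glycolysis and hypoxia genes, 6 were higher (median 0.46; adjusted p = 0.012), such as Egln3 (1.12), Vegfa (0.57) and Slc2a1 (0.54). Its adjusted p was 0.33 with an estimated correlation, and the other 2 lists were called that way. Adjusted over the list alone, 8 cell cycle genes were lower, and the numbers for the other 2 lists were the same. In limma 2495 genes were called, 1358 higher and 1137 lower, of which 184 differed at least 2-fold, and 1165 with median centring (shift 0). Within the 4 chips holding both groups the medians ranged from 0.33 to 0.53 for the stress response, from -0.43 to -0.17 for cell cycle and from -0.22 to 0.54 for glycolysis and hypoxia. The last changed sign on 1 chip and was not called with only these 2 groups in the fit (adjusted p = 0.0577) or on chips 1 to 4 alone (0.0992).

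**Figure D3:**
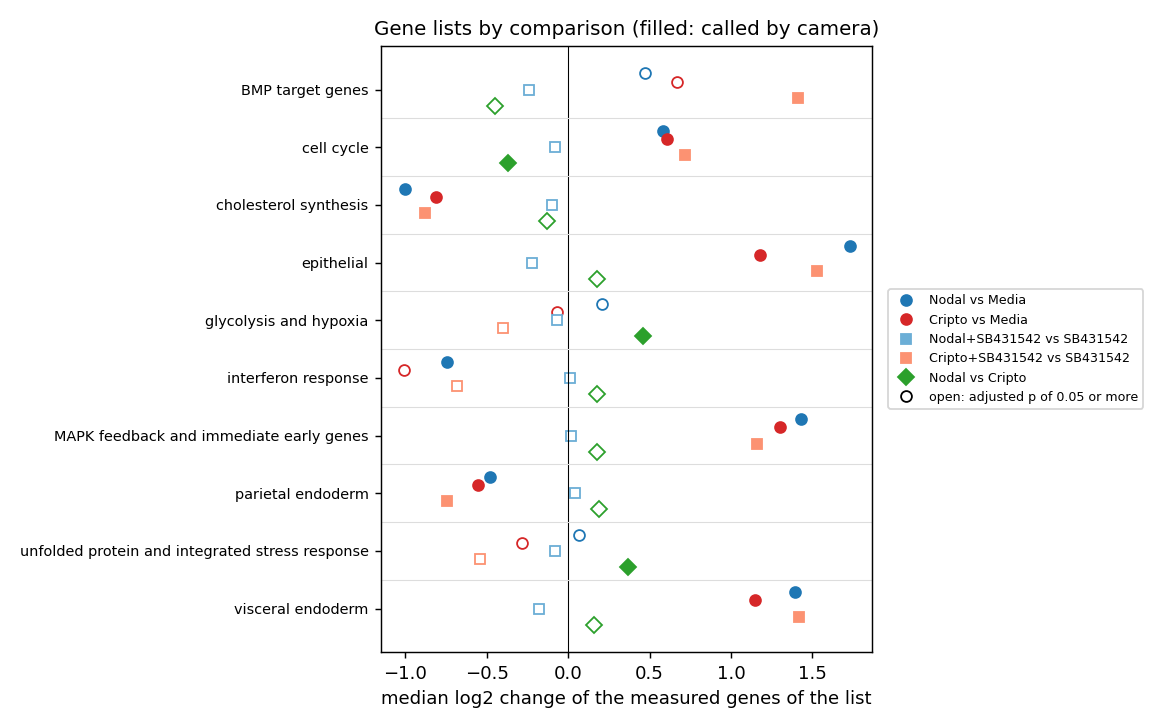
Median log2 change of the measured members (horizontal axis) of the 10 gene lists that camera called in any comparison, BMP targets among them, in 5 comparisons; filled symbols mark lists called by camera at the preset correlation and open symbols lists that were not. Nodal, Cripto and Cripto with SB431542 lie on the same side of 0 for all lists but the stress response and glycolysis and hypoxia, and Nodal with SB431542 against SB431542 lies between -0.24 and 0.04 in all 10.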

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

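The tests of added Nodal as the only cause, of wrong labels, of unresponsive RNA as the only cause and of brightness were chosen after the results were seen. Among 120 groups of samples, 17 had a sample far from the others, where 6 are expected, since chance marks about 1 in 20 groups.

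Most of these values came from chip 1, and all of those but the score of Cripto replicate 1 involved Nodal replicate 1. Nodal replicate 1 had a response score of 0.405 (the others 0.908 to 0.95) and Cripto replicate 1 a score of 0.853 (1.009 to 1.033). In Nodal replicate 1 the log2 level of Dpp4 was 9.623 (10.776 to 11.216) and that of Cldn6 11.238 (12.413 to 12.651). On chip 1 the difference between Nodal and Media was 4.501 for Dpp4 (5.748 to 6.233 on the other chips) and -6.717 for Igfbp5 (-4.265 to -4.046). The difference between Nodal and Cripto on chip 1 was 0.09 for Igfbp5, 0.856 for Msmb, 0.161 for Pygl, 1.07 for Vldlr, 0.493 for Stk32c, -0.373 for Lor, -0.194 for Mybpc3 and -0.608 for Map6, each closer to 0 than on the other chips. The level of Nid1 was 14.502 in Media replicate 5 (13.684 to 13.892), 14.671 in SB431542 replicate 5 (13.628 to 13.763) and 10.159 in Nodal replicate 2 (9.669 to 9.749).

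The response to Nodal differed with and without SB431542 by the interaction test, in 4365 genes. The largest interaction terms of the named genes were 5.98 for Pmch, 5.50 for Tmem176b, 5.31 for Sdk1, 5.04 for Nid1 and 4.78 for Tnik, and -6.54 for Cpn1, -6.23 for Gpc3, -5.76 for Car4, -5.64 for Cldn6 and -5.49 for Cyp26a1. These are fitted values, and several of the genes were not above background in a group. The interaction was also called for the lists of cell cycle (median -0.64), cholesterol synthesis (1.02), epithelial (-2.03), MAPK feedback (-1.36), parietal endoderm (0.52) and visceral endoderm genes (-1.64). With median centring the cell cycle value was -1.05. With an estimated correlation the adjusted p for cholesterol synthesis was 0.076. For Cripto the interaction was called in 65 genes, among them Taf15 (1.68), Prrc2c (1.61), Srp54a (1.12), Aptx (1.12), Gsn (1.11), Capza1 (-2.27), Tmem216 (-1.81), Ddx6 (-1.72), Gmfg (-1.69) and Hnrnpu (-1.63). None of the 3 other detected probes of Ddx6 had the same sign. The calls of these Cripto interaction genes were lost on 3 (Taf15) to 30 (Aptx) of the alternative settings, with omissions of 1 array included. Of the 2658 detected probes without a gene name, which no comparison of the report uses, limma called 1460 for Nodal against Media, 1616 for Cripto against Media and 1 for SB431542 against Media.

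The first pattern is the set of genes called for Nodal with SB431542 against SB431542 alone. In 538 genes chosen from chips 1 to 4, Media replicate 5 and SB431542 replicate 5 were shifted by 73.7% and 87.8% of the Nodal with SB431542 shift, beyond the SD of the other arrays (0.14 and 0.06, against a full shift of 1.78); this would speak against added Nodal as the only cause only if both arrays received no Nodal, so that cause stays open. A probe-position effect such as RNA fragmentation stays open, since other probes of the same genes changed by 39.3% as much (95% interval 29.2 to 53.7), against 74.8% (65 to 82.9) for Nodal genes matched in size. Wrong labels of those 2 arrays may also account for their shift: in genes chosen without the array measured, the mean shift of Media replicate 5 was 94.7% of the mean of the held-out Nodal with SB431542 arrays. Its shifts (1.01 to 1.04) lay below the least shifted of these (1.07) and those of SB431542 replicate 5 (1.09 to 1.12) above it, which leaves wrong labels open.

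The second pattern is the smaller response of Nodal replicate 1. Low brightness is argued against, because the dimmer Nodal replicate 4 had a score 0.85 higher (SD of replicates 2 to 5, 0.047). RNA of unresponsive cells as the only cause is argued against as well, since genes with the larger Cripto response changed 1.31 times as much in this array as in the Nodal group (95% interval 1.17 to 1.44; 0.93 to 1.02 in the other replicates). A mixture could still be part of the cause: its share of the full response was 0.66 for genes that rose and 0.85 for genes that fell, and the difference of -0.20 had an interval from -0.29 to 0.03. No biological explanation was tested.

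The third pattern is the brighter arrays of the responding groups. Brightness compared across chips is argued against as the cause of the response calls. The dim Nodal replicate 4 and Cripto replicate 4 scored at least 2.03 above each of 4 brighter Media arrays (largest group SD 0.379). Within chips, however, every Nodal array (1.05 to 2.09 times) and Cripto array (1.14 to 1.79 times) was brighter than its Media array. Arrays with the inhibitor argue against it as the only cause on chips 1 and 3. On chip 1 the Nodal with SB431542 array (629.1) scored -1.1. The dimmer Nodal (574.4) and Cripto (621.1) arrays scored 0.23 and 0.88. On chip 3 the SB431542 and Nodal with SB431542 arrays (519.7 and 519.2) scored -0.99 and -1.09. The dimmer Media array (433.6) scored -1.05. Brightness within a chip stays open as a part of the cause. With brightness as a covariate 3849 genes were called for Nodal and 4576 for Cripto, against 5727 and 6421 without it. Since brightness goes with treatment within chips, this drop does not separate the 2. A biological difference was not tested. Each sample was labelled from 200 ng of total RNA, so more RNA per cell would not by itself make an array brighter.

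The number of genes called was ranked among other splits of the same samples. At most 100 splits were compared, and they exchange arrays between chips, so a first rank does not exclude chance. The real split was the 1 of 100 with the most genes for Nodal against Media (5727; the highest other 4155), Cripto against Media (6421; 3870), Cripto with SB431542 against SB431542 (6521; 4259), Cripto with SB431542 against Cripto (856; 452), and Nodal against Cripto (2495; 1352). It was the 1 of 56 for Nodal with SB431542 against SB431542 (366; 88) and against Nodal (5338; 3172). Other splits also called genes, so the rank shows only that the real split was unusual among them. The count for Nodal with SB431542 against SB431542 ranged from 0 to 607 with 1 array left out, so it rests on single arrays. For the interactions the splits regroup arrays of 4 treatments, so a split carries treatment effects and does not measure chance: 1 of 100 called at least 4365 genes for Nodal (the real one; the highest other 4219) and 5 of 100 at least 65 for Cripto (the highest other 4783, which points to this structure of the samples). The share for Cripto does not exclude chance. For SB431542 against Media the comparison of splits says nothing, since 0 genes were called and all 100 splits must call at least as many.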

How the results depend on the processing

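Chips 1 to 4 alone, chips 5 to 7 alone, omission of chip 5, omission of Media replicate 5 with SB431542 replicate 5, and the brightness covariate were chosen after seeing the data. No paired analysis was possible because the replicate numbers follow only the order of the samples and pair none; the chip term compares arrays within chips instead. The genes named for Nodal against Media, Cripto against Media and Cripto with SB431542 against SB431542 kept direction and call on all 320 gene and setting pairs each, and on all 200 with 1 array left out. Counts stayed within 1.5 times in 244 cases and moved in 86, and with 1 array left out in 192 and 51. The 35 called lists kept their direction on every setting that gave them a value (23 of them on chips 5 to 7). Their median moved by over 1.5 times for 19 without background correction, 22 with the deposited values, 13 without the filter and 9 with median centring, and for at most 1 on the others. List calls gained on other settings numbered 19 for Cripto against Media, 3 for Nodal against Media, 5 for SB431542 against Media, 6 for Cripto with SB431542 against SB431542, 4 for Nodal with SB431542 against Nodal, 8 for Nodal against Cripto and 5 for the Nodal interaction.

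With all probes tested singly, which tests more features, counts were 10242 for Nodal against Media, 11507 for Cripto against Media, 675 for Nodal with SB431542 against SB431542, 11794 for Cripto with SB431542 against SB431542, 9673 for Nodal with SB431542 against Nodal, 1458 for Cripto with SB431542 against Cripto, 3768 for Nodal against Cripto, 7755 and 100 for the Nodal and Cripto interactions, and 8725 for the overlap. For the other settings the cause was not tested. Nodal with SB431542 against SB431542 gave 76 genes with median centring, 227 without the filter, 3 without the chip term, 1594 with only these groups, 711 without chips 6 and 7, 43 without chip 5 and 818 without the 2 doubted arrays. With median centring Slc6a15 reversed in it (-0.40, adjusted p = 0.732). Cripto with SB431542 against Cripto gave 305 with median centring, 177 without the chip term, 86 with only these groups, 243 without chips 6 and 7, 34 on chips 1 to 4, 52 on chips 5 to 7 and 505 without chip 5. Nodal against Cripto gave 1165 with median centring, 1234 without the chip term, 626 with only these groups, 861 on chips 1 to 4 and 1154 on chips 5 to 7. Nodal with SB431542 against Nodal gave 1661 with only these groups. The overlap was 3173 with the brightness covariate. The Cripto interaction gave 146 without background correction, 2 with median centring, 139 with the deposited values, 39 without the filter, 2 without the chip term, 4 without chips 6 and 7, 0 on chips 1 to 4, 0 on chips 5 to 7, 5 without chip 5 and 16 without the 2 doubted arrays. The mean change of Nodal response genes under SB431542 was -0.042 without the chip term (exact p = 0.0179) and -0.074 with the brightness covariate (exact p = 0.0357). That of Cripto response genes was 1.068 on chips 1 to 4 (exact p = 0.1) and 1.121 on chips 5 to 7 (exact p = 0.333), where the arrays are too few to pass 0.05. Chips 5 to 7 hold no Nodal with SB431542 array and give no value for it.

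With 1 array left out, counts ranged from 5302 to 6158 for Nodal against Media, 6085 to 6248 for Cripto against Media, 0 to 1 for SB431542 against Media, 0 to 607 for Nodal with SB431542 against SB431542, 6033 to 6508 for Cripto with SB431542 against SB431542, 4544 to 5856 for Nodal with SB431542 against Nodal, 249 to 1025 for Cripto with SB431542 against Cripto, 1986 to 2863 for Nodal against Cripto, 3736 to 5041 and 9 to 216 for the Nodal and Cripto interactions, and 4553 to 5171 for the overlap. The retained change ranged from -0.053 to -0.001 for Nodal (exact p 0.143 to 0.982) and from 0.961 to 1.005 for Cripto (0.00794 to 0.0159). Signal over background limits genes not above background to bounds.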

Other observations

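Genes outside the called lists also moved with both proteins. Gata6 (log2 change 0.03, adjusted p = 0.772) and Gata4 (-0.13, adjusted p = 0.556), transcription factors of primitive endoderm, were not called for Nodal against Media. Klf6 rose by 1.07 with Nodal and 2.15 with Cripto, and Foxq1 by 1.33 and 1.54. The trophoblast gene Gata3 was lower with both (-4.02 and -3.81; detected on 1 of 5 arrays of each, at means of 5.49 and 5.73 against a lowest detection floor of 5.55, so the size is uncertain), and the Wnt target Axin2 at least 6.01-fold and 5.65-fold. Of Nodal pathway genes, Acvr1b, which encodes Alk4, was higher (1.20 and 1.03), and the EGF-CFC gene Cfc1 was lower (-2.29 and -2.12; detected on 3 of 5 arrays of each). Of Smad2/3 targets, Gadd45b (1.84 and 3.44) and Tnfrsf12a (2.54 and 3.47) were higher and Cdkn2b (-1.94 and -2.14) and Fn1 (-1.35 and -1.70) lower. Cer1, Lefty1, Otx2, Nodal and Tdgf1 had probes on the array but did not pass the detection filter.

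The other lists were not called by limma's camera for either protein, and are given as the median log2 change and adjusted p for Nodal and then Cripto against Media. The values were -0.39 (0.19) and -0.49 (0.051) for basement membrane, 0.47 (0.15) and 0.67 (0.051) for BMP targets, -0.24 (0.83) and -0.07 (0.76) for anterior visceral endoderm, -0.14 (0.9) and -0.06 (0.76) for fibroblast feeder genes, and 0.21 (0.61) and -0.07 (0.76) for glycolysis and hypoxia. They were -0.13 (0.64) and -0.47 (0.82) for mesenchymal genes, 0.25 (0.88) and 0.15 (0.76) for mesendoderm, -0.11 (0.88) and -0.13 (0.76) for Nodal pathway components, -0.38 (0.88) and 0.07 (0.95) for pluripotent epiblast, and -0.05 (0.88) and -0.07 (0.95) for primitive endoderm transcription factors. They were -0.19 (0.71) and -0.41 (0.76) for Smad2/3 targets, 0.37 (0.88) and 1.5 (0.61) for trophoblast, 0.07 (0.57) and -0.28 (0.19) for the stress response, and -0.05 (0.64) and 0.22 (0.76) for Wnt targets. The interferon response had -1.01 (0.052) with Cripto. Some lists rest on few measured genes: 3 each for fibroblast feeder, mesendoderm and Wnt targets and 4 for anterior visceral endoderm. BMP targets, pluripotent epiblast and trophoblast had 5 each. For such lists the lack of a call says little about the other listed genes. Several of the lists not called lie close to the threshold and were called on other settings. Basement membrane was called for Cripto on 8 settings (adjusted p of 0.00034 to 0.0492) and 6 of the fits with 1 array left out (0.0384 to 0.0494), and for Nodal on 3 settings (0.00151 to 0.019). With Cripto, BMP targets were called on 5 settings (0.0417 to 0.0492) and 7 such fits (0.0423 to 0.0494), the interferon response on 5 (0.02 to 0.0496) and 3 such fits (0.0423 to 0.0492), and the stress response on 1 (0.0188).

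Adjusted over the list alone, 11 in place of 10 basement membrane genes fell and 4 in place of 3 BMP targets rose with Nodal, and the other numbers were the same. With genes not above background at their bound, the medians were 0.37 for BMP targets, 0.07 for glycolysis and hypoxia, 0 for mesendoderm, -0.05 for Nodal pathway components, -0.01 for Smad2/3 targets and 0 for trophoblast with Nodal. With Cripto they were -0.49 for the interferon response, -0.08 for glycolysis and hypoxia, -0.14 for Nodal pathway components, -0.07 for Smad2/3 targets, 0.51 for trophoblast and 0 for Wnt targets. The mean had the other sign than the median for Nodal pathway components (0.03), primitive endoderm transcription factors (0.10) and trophoblast (-0.24) with Nodal. With Cripto it did for pluripotent epiblast (-0.12), primitive endoderm transcription factors (0.10) and Wnt targets (-0.77). The direction given by camera followed the mean in these cases except trophoblast with Nodal, where it pointed up and that of fry down.

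The fry test asks whether the genes of a list move on balance in 1 direction and does not compare them with other genes. It called every list that camera called, and 16 lists in all for Nodal against Media, 16 for Cripto against Media, 17 for Cripto with SB431542 against SB431542, 14 for Nodal with SB431542 against Nodal, 14 for Nodal against Cripto and 14 for the Nodal interaction. The 9 lists called by fry alone for Nodal against Media were, with adjusted p, basement membrane (lower, 1.3e-11), BMP targets (higher, 5.9e-07), trophoblast (lower, 3.6e-06), Wnt targets (lower, 1.7e-05), the stress response (higher, 1.9e-05), mesenchymal genes (lower, 0.00077), primitive endoderm transcription factors (higher, 0.001), Smad2/3 targets (lower, 0.0016) and glycolysis and hypoxia (higher, 0.029). The 10 for Cripto against Media were basement membrane (lower, 6.6e-15), BMP targets (higher, 6e-10), the interferon response (lower, 3.3e-09), the stress response (lower, 9e-09), Wnt targets (lower, 0.00011), primitive endoderm transcription factors (higher, 0.00072), mesendoderm (higher, 0.0021), anterior visceral endoderm (lower, 0.003), Nodal pathway components (lower, 0.011) and mesenchymal genes (lower, 0.049).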
